A study of Mus musculus with 24 samples.

How the data were processed

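Organoids grown from mouse small intestine are self-organising cultures of intestinal epithelium that hold stem cells and their differentiated descendants. Polyadenylated RNA was sequenced from 24 such samples. They fall into 6 groups of 4 by treatment and time: DMSO (vehicle), dFz7-21 or Fz7-21S, each at 6 h and at 24 h. The series design describes dFz7-21 as a peptide that blocks Frizzled 7, a Wnt receptor. The labels give no dose, no medium and nothing about Fz7-21S except its name. RNA was isolated with the RNeasy Micro kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

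The authors deposited 1 file per sample with 36528 Entrez gene IDs and 2 values for each. The deposited count is the number of reads that align uniquely to the gene model, per the file headers. The deposited RPKM is adjusted by a size factor for each sample, per the file headers. GSNAP and the mouse build GRCm38 are named in the submitters' processing notes. The version of the aligner, the annotation, the counting of strand and the filters are not given in the sources used here. The ratio of RPKM to count between 2 libraries was constant over genes (largest CV 2.4e-15), so the RPKM hold no information beyond the counts and the gene length, and they entered no test. Unique alignment can lose reads of near-identical genes. Id3, whose values 2 other gene models repeat, and overlapping pairs such as Prn and Prnd are reported as uncertain, and reads of antisense partners cannot be told apart without strand.

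Symbols were paired through the RefSeq gene table of GRCm38 (31049 IDs) and the GENCODE table of Entrez IDs (77 IDs). The other 5402 IDs, with 2.54% to 3.50% of the counts of a library, stayed in the tests without a name. Positions are those of the RefSeq genes on GRCm38, counted from 1, and each value belongs to the whole gene model. Total counts ran from 20.4 M to 33.1 M per library (median 25.1 M). A count of 3 corresponds to 0.0906 to 0.147 CPM (counts scaled to a common library size), which is the floor used here for a gene without reads. The floor covers counting error only, while the intervals of log2 fold changes come from the spread between libraries. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom between replicates ran from 2.86 to 96.1. The labels do not say that replicates are separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

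The counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM factors) in R 4.3.3. Genes were kept by filterByExpr on the 6 groups, which left 15429 genes. A single fit of all 24 libraries, with a coefficient for each group, gave every contrast. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. Levels are TMM-normalised CPM, as mean ± SD with n = 4, and log2 fold changes are given ± SE. The comparisons were dFz7-21 against DMSO, dFz7-21 against Fz7-21S and Fz7-21S against DMSO at each time, DMSO at 24 h against 6 h, and the change of the dFz7-21 effect from 6 h to 24 h as an interaction term.

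Gene lists (23) were fixed before the data were examined, as were the groups, the tests, the other settings tried and the rule for named genes. They cover Lgr5 stem cells, Wnt targets, Wnt receptors and ligands, reserve and injury stem cells, enterocytes, goblet cells, Paneth cells, enteroendocrine cells, tuft cells, the cell cycle, the Notch pathway, unfolded protein and integrated stress responses, p53 targets, interferon and NF-kB responses, immediate early genes, cholesterol synthesis, oxidative and metal stress, glycolysis and hypoxia, BMP and TGF-beta targets, mesenchymal cells, immune cells, endothelial and glial cells, and sex-linked genes. The stem cell and Wnt target lists share 11 members. Lists were tested with camera (limma 3.58.1, two-sided, inter-gene correlation preset at 0.01) on log2 CPM with a prior count of 2. The 138 tests of 23 lists in 6 comparisons were adjusted together, and those of DMSO over time were adjusted on their own. Each list test was repeated with an estimated correlation and with fry, which asks whether members move one way on balance and does not compare them with other genes.

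The rule for named genes took, for each comparison of 2 groups, the 8 that rose and the 8 that fell most among called genes with a mean log2 CPM of at least 2, no overlap between the replicates of the 2 groups and an established symbol (5 and 5 for DMSO over time). It added Lgr5, Ascl2, Axin2, Olfm4, Smoc2, Sp5, Nkd1, Rnf43, Znrf3, Myc, Fzd7, Mki67, Alpi, Muc2, Lyz1, Chga and Dclk1 whatever their result. It also took the 4 members of a described list with the smallest p, and for the interaction the 5 genes with the smallest p.

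The other settings tried were RLE size factors, no filter on low counts, the replicate number as a block, a minimum fold of 1.2 (glmTreat), a fit of only the groups compared, limma-voom, DESeq2 1.42.0, and leaving out each library in turn. Leaving out a library is reported only for the comparisons that hold it, except in the total of list calls. The steps were tested on counts simulated from these libraries. For dFz7-21 against DMSO at 24 h, with 15206 genes, 26% of the genes changed 1.25-fold were recovered, 60% of those changed 1.5-fold, 82% of those changed 2-fold and 88% of those changed 4-fold, with 50 genes at each size. Of 134 calls in that simulation 6 were false, and of 107 calls for the change between times 7 were false (6.54%). For Fz7-21S against DMSO at 24 h, with 0 genes changed, 1 was called. The simulated counts hold a single spread per gene, with no outlying library and no correlation between genes, so these rates may not carry over to the data. When only the stem cell list was shifted, the Wnt target list was called as well. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.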

Results

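Gene expression was measured by sequencing of polyadenylated RNA in organoids from mouse small intestine, 4 replicates for each of DMSO, dFz7-21 and Fz7-21S at 6 h and at 24 h. Counts per gene summed to between 20.4 M (DMSO 24 h replicate 2) and 33.1 M (DMSO 24 h replicate 1) per library. Of the 36528 genes in the files, 15429 had enough reads to be tested. The study asks how expression in intestinal epithelium responds when Frizzled 7 is blocked. The first principal component, with 48.3% of the variance, parted the 6 h from the 24 h libraries. Transcripts of mesenchymal cells, which are not part of the epithelium, were present in 3 libraries: DMSO 6 h replicates 1 and 2 and dFz7-21 24 h replicate 3. Col1a1, a fibrillar collagen chain (chromosome 11, 94936224 to 94953042), stood at 80.6, 10.2 and 395 CPM there and at 0.657 CPM or less in the other 21. Vim, the intermediate filament of mesenchymal cells, stood at 53.3, 100.1 and 257 CPM there, against 6.74 CPM or less in the other 21.

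**Figure D1:**
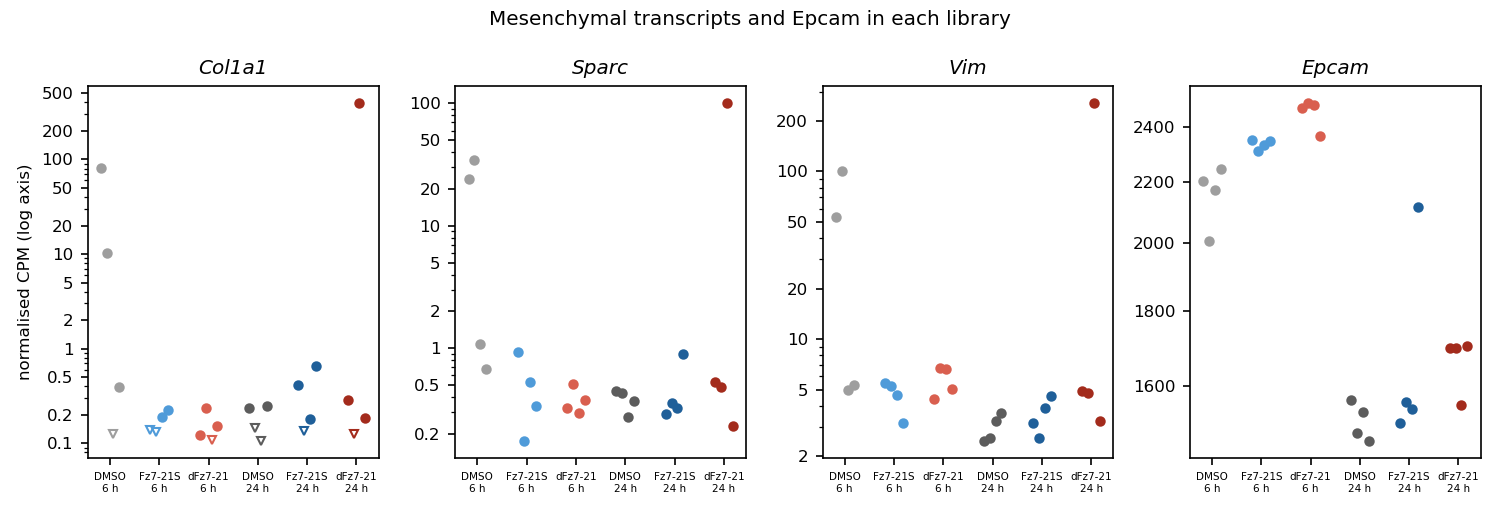
Normalised CPM (log axis) of Col1a1, Sparc, Vim and Epcam in each of the 24 libraries by group; points are libraries and open triangles lie below the floor of 3 counts and are drawn at it. Col1a1 reaches 395 CPM in dFz7-21 24 h replicate 3 and 80.6 CPM in DMSO 6 h replicate 1, and does not exceed 0.657 CPM in the 21 libraries other than those and DMSO 6 h replicate 2.

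After 24 h with dFz7-21, transcripts of the intestinal stem cell such as Lgr5 and Olfm4 were much lower in the organoids, while Alpi of absorptive cells and Muc2 of goblet cells were higher. Lgr5, the R-spondin receptor that marks stem cells at the crypt base (chromosome 10, 115450314 to 115587780), was 25.4-fold lower than with DMSO. It fell from 97.0 ± 19.3 to 3.82 ± 1.24 CPM (SD, n = 4), a log2 change of -4.67 ± 0.20. Olfm4, a secreted glycoprotein abundant in the same cells (chromosome 14, 80000302 to 80023141), was 20.1-fold lower, at 67.9 ± 18.1 against 1367 ± 226 CPM. Fabp6, the ileal bile acid-binding protein (chromosome 11, 43596040 to 43601562), was 7.33-fold higher, at 121 ± 17.9 against 16.5 ± 2.81 CPM. The adjusted p were 5.36e-14 for Lgr5, 7.79e-16 for Olfm4 and 1.18e-10 for Fabp6. No library of one group overlapped the other group for these genes.

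Among called genes with a mean log2 CPM of at least 2 and no overlap between replicates, the others that fell most at 24 h by the rule for named genes were Pcdh8, a protocadherin (log2 change -3.62 ± 0.26), Cbs, the cystathionine beta-synthase of sulfur amino acid metabolism (-2.96 ± 0.12), Ccdc3 (-2.81 ± 0.18), Pik3ap1 (-2.71 ± 0.16), Angpt2, an angiopoietin (-2.67 ± 0.14), and Msi1, an RNA-binding protein of stem and progenitor cells (-2.46 ± 0.13). Among those chosen by that rule for their rise were Reg3b, an antimicrobial lectin (2.25 ± 0.19), Ces1g, a carboxylesterase (1.79 ± 0.08), Pyy, a gut peptide hormone (1.74 ± 0.29), Oasl2 and Isg15, both induced by interferon (1.72 ± 0.26 and 1.69 ± 0.43), Fcgrt, the neonatal Fc receptor (1.72 ± 0.16), and Zg16, a lectin of goblet cell granules (1.62 ± 0.14). In all, 5537 genes passed the test, 2804 higher and 2733 lower with dFz7-21. Most changes were small: the median absolute log2 change of called genes was 0.41, and 369 genes rose and 371 fell at least 2-fold.

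Of the 34 tested members of the Lgr5 stem cell list, 31 fell and 3 rose at 24 h, and the same counts held adjusted over the list alone. The list median was -1.42 on the log2 scale (camera adjusted p = 7.02e-28). The transcription factor Ascl2, which maintains these stem cells, fell by 1.51 on the log2 scale, and the matricellular protein Smoc2 fell by 2.11, from 584 ± 44.4 to 135 ± 13.4 CPM. Rgmb, a BMP co-receptor, fell by 1.78. The 3 members that rose, named after their values were seen, were Fstl1, Vdr and Phgdh. Fstl1 stood at 47.0 CPM in dFz7-21 24 h replicate 3, where mesenchymal transcripts were present, and at 0.193 CPM or less in the other 3 libraries of that group. Without the 3 libraries with mesenchymal transcripts, 32 members fell and 2 rose.

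Targets of Wnt signalling, of which 11 are also on the stem cell list, were lower at 24 h: 21 of 26 tested members of the Wnt target list were lower and 3 higher (median -0.97, camera adjusted p = 1.69e-12), with the same counts adjusted over the list alone. In a test chosen after these values were seen, of the 15 members that are not on the stem cell list 10 fell and 3 rose, as adjusted over the list alone (median -0.50, camera adjusted p = 0.000912, but adjusted p = 0.0564 with an estimated correlation). Axin2, a negative feedback regulator of the pathway, was at 93.8 ± 16.2 against 271 ± 19.3 CPM (log2 change -1.53 ± 0.11). Sp5, a transcription factor induced by Wnt, changed by -2.34 ± 0.16, Nkd1, an inhibitor of the pathway, by -1.15 ± 0.26, and Ephb3, a receptor that positions crypt cells, by -1.54 ± 0.08. The ubiquitin ligases Rnf43 and Znrf3, which remove Frizzled receptors from the cell surface, fell by 1.04 and 0.82 on the log2 scale, and Myc fell by 0.50. Notum, Id2 and Cdx2 were the members that rose, named after their values were seen. Fzd7 itself (chromosome 1, 59482147 to 59486955) was at 30.2 ± 7.00 CPM with dFz7-21 and at 52.0 ± 4.66 CPM with DMSO (-0.78 ± 0.12, adjusted p = 1.6e-05). In the list of Wnt receptors and ligands 10 of 23 members fell and 1 rose (median -0.35, camera adjusted p = 0.00616), with the same counts adjusted over the list alone. That call was lost at an adjusted p = 0.379 with an estimated correlation.

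**Figure D2:**
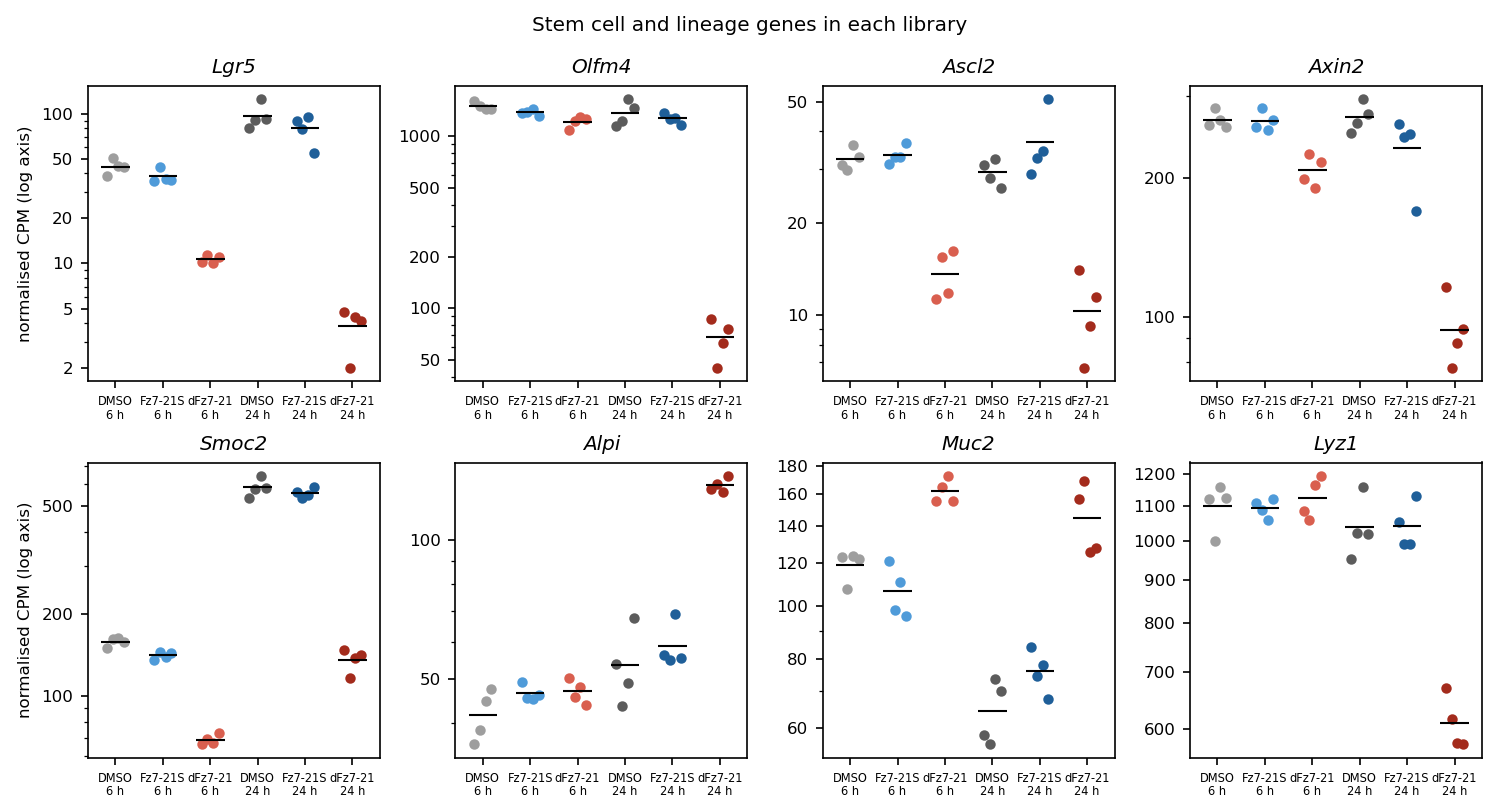
Normalised CPM (log axis) of Lgr5, Olfm4, Ascl2, Axin2, Smoc2, Alpi, Muc2 and Lyz1 by treatment and time; points are libraries and lines are group means (n = 4). Lgr5 and Ascl2 lie below both other groups at both times with dFz7-21, while Olfm4 falls to 67.9 CPM only in the 24 h group.

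The lineages did not move together at 24 h. Of 33 enterocyte genes 30 rose and 1 fell (median 0.71, camera adjusted p = 1.81e-13, but adjusted p = 0.15 with an estimated correlation), the same counts as adjusted over the list alone. The brush border phosphatase Alpi rose from 53.6 ± 10.4 to 131 ± 4.54 CPM (log2 change 1.29 ± 0.10), the keratin Krt20 by 0.85 ± 0.08 and the lectins Reg1 and Reg3a by 1.94 ± 0.21 and 1.47 ± 0.13. Of 23 Paneth cell genes 17 fell and 0 rose (median -0.48, camera adjusted p = 3.51e-07, but adjusted p = 0.312 with an estimated correlation), with 17 lower adjusted over the list alone. Lyz1, the lysozyme of Paneth granules, fell from 1037 ± 86.7 to 610.2 ± 44.5 CPM, and Defa3, an antimicrobial defensin of a family with near-identical copies, fell by 1.65 on the log2 scale. Goblet cell genes went both ways: 9 of 20 rose and 3 fell (9 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0823, but 0.0395 without DMSO 24 h replicate 3 and 0.0341 without dFz7-21 24 h replicate 4). The gel-forming mucin Muc2 rose by 1.17 ± 0.10 and the secreted Clca1 from 33.8 ± 2.61 to 77.8 ± 12.0 CPM, while the transcription factor Foxa3 fell by 1.14 on the log2 scale.

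Among 30 enteroendocrine genes 7 rose and 5 fell, the same counts as adjusted over the list alone, and the list did not pass (camera adjusted p = 0.554). Neurog3, the transcription factor that starts the lineage, fell 3.99-fold, to 7.11 ± 0.982 CPM, and Insm1, which acts after it, fell by 0.96 on the log2 scale. The granule protein Chga rose by 0.70 ± 0.11 and the hormone secretin, Sct, by 1.45 ± 0.21. Tuft cell genes held 2 that rose and 1 that fell out of 23, also adjusted over the list alone (camera adjusted p = 0.458). Pou2f3, the lineage's transcription factor, fell by 1.01 on the log2 scale, while Dclk1 was at 9.06 ± 0.727 against 7.62 ± 1.30 CPM and did not pass (adjusted p = 0.281, 95% interval of the log2 change -0.11 to 0.60).

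Of 40 cell cycle genes 28 fell and 0 rose at 24 h, as adjusted over the list alone (median -0.23, camera adjusted p = 6.18e-10, but adjusted p = 0.0564 with an estimated correlation). The members with the smallest p included Mcm6 (-0.58 ± 0.05), Mcm2 (-0.66 ± 0.06) and Cdc6 (-0.69 ± 0.06). The proliferation marker Mki67 did not pass, with a 95% interval of -0.43 to 0.07. Cholesterol synthesis genes rose in 18 of 25 cases and fell in 0, as adjusted over the list alone (median 0.28, camera adjusted p = 1.58e-07). Hmgcs1, which makes the precursor of mevalonate, rose by 0.41 ± 0.06, and the sterol sensor Insig1 by 0.44 ± 0.07. Genes of oxidative and metal stress rose in 16 of 26 cases and fell in 3, with 18 and 3 adjusted over the list alone (median 0.58, camera adjusted p = 3.51e-07, but adjusted p = 0.0628 with an estimated correlation). Srxn1 and Nqo1, both targets of the antioxidant factor Nrf2, rose by 0.84 ± 0.06 and 0.80 ± 0.06. Genes of the unfolded protein and integrated stress responses rose in 15 of 26 cases and fell in 1, as adjusted over the list alone (camera adjusted p = 6.25e-06, but adjusted p = 0.0559 with an estimated correlation), among them Chac1 by 0.87 ± 0.07 and Trib3 by 0.88 ± 0.08.

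Further lists at 24 h passed with the preset correlation and were lost with an estimated one. Notch pathway genes fell in 11 of 18 cases and rose in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.000401, adjusted p = 0.138 with an estimated correlation), with the modulator Lfng at -1.55 ± 0.12 and the ligand Dll1 at -0.86 ± 0.09. Interferon and NF-kB genes rose in 14 of 31 cases and fell in 1 (15 and 1 adjusted over the list alone, camera adjusted p = 0.000441, adjusted p = 0.225 with an estimated correlation), among them Irf7 by 0.82 ± 0.11. Glycolysis and hypoxia genes rose in 10 of 25 cases and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 0.000622, adjusted p = 0.49 with an estimated correlation), led by Pfkp at 0.72 ± 0.06. BMP and TGF-beta targets rose in 11 of 19 cases and fell in 2 (11 and 3 adjusted over the list alone, camera adjusted p = 0.0439, adjusted p = 0.47 with an estimated correlation). Id3, whose value is uncertain because 2 other gene models hold the same values, and Smad6, both induced by BMP, rose by 1.27 ± 0.12 and 1.64 ± 0.20, while Bmp7 fell by 1.06 and Bambi by 1.08 on the log2 scale. The list call was lost without dFz7-21 24 h replicate 3 (adjusted p = 0.288), the library of that group with mesenchymal transcripts.

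The remaining lists did not pass at 24 h. Reserve and injury stem cell genes went both ways, 5 up and 5 down of 23 (6 and 6 adjusted over the list alone), with Clu at -1.34 ± 0.12 and the growth factor Ereg at 0.89 ± 0.10. Their median (0.06) and mean (0.29) were positive while camera pointed down (adjusted p = 0.801). Their score was 5.59 in dFz7-21 24 h replicate 3, which holds mesenchymal transcripts, against 4.81 or less in the other 3 libraries of the group and 4.76 to 5.11 in DMSO. Without the 3 libraries with mesenchymal transcripts 4 of these genes rose and 10 fell. Of 24 p53 targets 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.231), with Cdkn1a higher by 0.72 ± 0.08. The p53 score was 5.90 in dFz7-21 24 h replicate 3 and 5.61 to 5.62 in the rest of the group. Of 27 immediate early genes 10 rose and 7 fell (11 and 7 adjusted over the list alone, camera adjusted p = 0.554), with a score of 4.27 in dFz7-21 24 h replicate 3, 3.75 to 3.83 in the rest of the group and 3.82 to 3.87 in DMSO. Leaving out the 3 libraries with mesenchymal transcripts, 5 p53 targets rose and 4 fell, and 9 immediate early genes rose and 9 fell. All 7 mesenchymal genes called, out of 8 tested, were higher, and the list did not pass (camera adjusted p = 0.172, but 0.0465, 0.0316 and 0.0253 without dFz7-21 24 h replicate 1, 2 and 4). Col1a1 reached 395 CPM in replicate 3 of that group alone. Of 4 immune genes Itgam rose and 0 fell (camera adjusted p = 0.811). Of 9 endothelial and glial genes 4 fell, led by Esam at -1.55 ± 0.17, and Lyve1 rose (camera adjusted p = 0.267). The counts of these 3 lists did not differ when adjusted over the list alone. Of 4 sex-linked genes 0 were called at either adjustment with edgeR (camera adjusted p = 0.607).

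**Figure D3:**
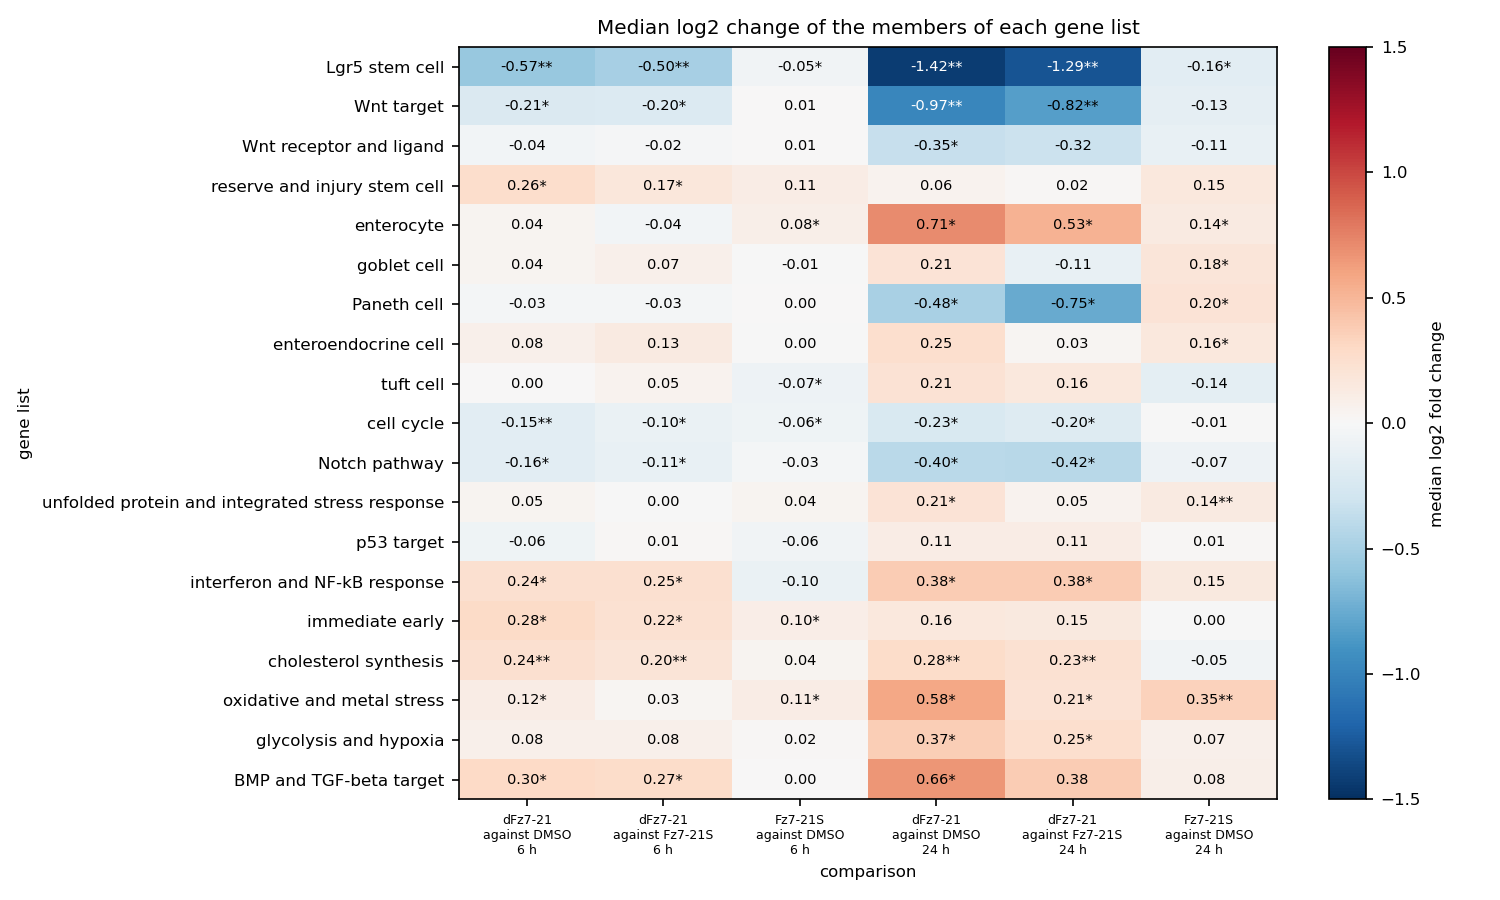
Median log2 fold change of 19 fixed gene lists in each of 6 comparisons; 1 asterisk marks a camera adjusted p below 0.05 with the preset correlation, and a pair of asterisks a list that also passed with an estimated correlation. The stem cell list passes both ways in the 4 comparisons with dFz7-21, with a median of -1.42 against DMSO at 24 h.

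The calls that held with an estimated correlation in the 6 treatment comparisons numbered 13 of 57. They were the stem cell list (adjusted p = 0.00902 in each of the 4 comparisons with dFz7-21), the Wnt target list at 24 h against both DMSO and Fz7-21S (0.0245 in both), and cholesterol synthesis in the 4 comparisons with dFz7-21 (0.0279 and 0.00911 against DMSO at 24 h and 6 h, 0.0212 and 0.00911 against Fz7-21S). The others were the cell cycle list against DMSO at 6 h (0.0499), and, for Fz7-21S against DMSO at 24 h, oxidative and metal stress (0.0159) and unfolded protein and integrated stress (0.0308).

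After 6 h with dFz7-21, Lgr5 and other stem cell transcripts were already lower than with DMSO, and Id1, Id2 and Id3 were higher. Lgr5 was 4.15-fold lower, at 10.7 ± 0.602 against 44.4 ± 4.84 CPM (SD, n = 4, log2 change -2.05 ± 0.18, adjusted p = 3.65e-08). Pcdh8 was 7.71-fold lower (-2.95 ± 0.29). The inhibitors of DNA binding Id1 (chromosome 2, 152736251 to 152737410), Id2 and Id3, targets of BMP signalling that hold back differentiation factors, rose by 1.47 ± 0.13, 1.27 ± 0.07 and 1.51 ± 0.12. The value of Id3 is uncertain because 2 gene models on chromosome 17 hold the same values. In all, 1705 genes passed the test, 934 higher and 771 lower, of which 42 rose and 31 fell at least 2-fold.

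Other genes chosen for their rise at 6 h, by the rule that asks for a mean log2 CPM of at least 2 and no overlap between replicates, were Epb41l1, a cytoskeletal adaptor (1.40 ± 0.11), the retinaldehyde dehydrogenase Aldh1a3 (1.28 ± 0.12), the ceramidase Acer1 (1.27 ± 0.16), Sct (1.26 ± 0.21) and Sprr2a3 (1.22 ± 0.15). Others chosen for their fall were the receptor phosphatase Ptpro (-1.83 ± 0.19), Rgcc (-1.81 ± 0.18), the sodium channel subunit Scn2b (-1.66 ± 0.14), Sp5 (-1.48 ± 0.15), the phospholipase Pla2g5 (-1.41 ± 0.15) and Sema4c (-1.34 ± 0.15). Ascl2 was 2.37-fold and Smoc2 2.30-fold lower, and Muc2 rose by 0.45 ± 0.10. Olfm4 was at 1218 ± 91.7 against 1501 ± 75.7 CPM and did not pass (adjusted p = 0.146, 95% interval of the log2 change -0.56 to -0.04). Nkd1, Znrf3, Fzd7, Mki67, Alpi, Lyz1, Chga and Dclk1 did not pass either, the interval of Fzd7 running from -0.20 to 0.29. Axin2 (-0.36, adjusted p = 0.0292), Rnf43 (-0.26, adjusted p = 0.00573) and Myc (-0.15, adjusted p = 0.0358) passed. Axin2 no longer passed without DMSO 6 h replicate 1, 2 or 3 or dFz7-21 6 h replicate 1 or 3 (adjusted p from 0.0525 to 0.108), nor Myc without any 1 of the DMSO 6 h libraries or dFz7-21 6 h replicate 1, 3 or 4 (0.0503 to 0.12). Without the 3 libraries with mesenchymal transcripts Rnf43 and Muc2 no longer passed (adjusted p = 0.0839 and 0.0604). The count was 698 without those 3 libraries and 2236 without them, Fz7-21S 24 h replicate 4 and DMSO 24 h replicate 2. Both settings keep the same 6 h libraries, with DMSO 6 h replicates 3 and 4 as the only controls. The counts differ by 24 h libraries outside the comparison, which enter it only through the shared fit. The drop to 698 is therefore not explained by fewer controls or mesenchymal transcripts alone, and these were not tested apart.

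Of the 34 stem cell list genes 23 fell and 0 rose at 6 h (27 lower adjusted over the list alone, median -0.57, camera adjusted p = 3.76e-26), including the receptor antagonist Lrig1 at -0.77 ± 0.07. Without the 3 libraries with mesenchymal transcripts 17 fell. Of 26 Wnt targets 12 fell and 2 rose (13 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 1.94e-05, but adjusted p = 0.169 with an estimated correlation), with Tnfrsf19 at -1.30 ± 0.13. Of the 15 members that are not on the stem cell list 3 fell and 2 rose, as adjusted over the list alone, and they did not pass (median 0.04, mean 0.02, camera pointing down, adjusted p = 0.819). Of all 26 Wnt targets 7 fell and 2 rose without the 3 libraries with mesenchymal transcripts. Of 40 cell cycle genes 18 fell and 0 rose (18 and 2 adjusted over the list alone, median -0.15, camera adjusted p = 8.13e-11). Mcm6 and Mcm5 each changed by -0.56 ± 0.05. Of 25 cholesterol synthesis genes 14 rose and 0 fell (18 higher adjusted over the list alone, median 0.24, camera adjusted p = 7.66e-11). Without the 3 libraries with mesenchymal transcripts 12 cell cycle genes fell and 6 cholesterol synthesis genes rose.

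BMP and TGF-beta targets rose in 8 of 19 cases and fell in 1 at 6 h (10 and 2 adjusted over the list alone, camera adjusted p = 1.62e-05, but adjusted p = 0.0811 with an estimated correlation), with Smad6 at 1.58 ± 0.19. Immediate early genes rose in 12 of 27 cases and fell in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 2.69e-06, but adjusted p = 0.123 with an estimated correlation), with Junb at 0.57 ± 0.09 and Fos at 0.44 ± 0.07. Reserve and injury stem cell genes rose in 10 of 23 cases and fell in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.000322, but adjusted p = 0.259 with an estimated correlation), with Ereg at 0.66 ± 0.09 and Sprr1a at 1.01 ± 0.14. Their score was 5.81 and 5.74 in DMSO 6 h replicates 1 and 2, which hold mesenchymal transcripts. It was 5.44 and 5.57 in DMSO 6 h replicates 3 and 4 and 5.75 to 5.83 with dFz7-21. Interferon and NF-kB genes rose in 7 of 31 cases and fell in 0 (8 and 2 adjusted over the list alone, camera adjusted p = 0.00292, but adjusted p = 0.324 with an estimated correlation), their median at 0.24 and their mean at -0.03. Their score was 3.68 in DMSO 6 h replicate 2, which holds mesenchymal transcripts, 2.92 to 3.12 in the other 3 DMSO libraries and 3.19 to 3.32 with dFz7-21. Nfkbia, the inhibitor of NF-kB, rose by 0.41 ± 0.06. Of 8 mesenchymal genes 0 were called with edgeR (6 lower adjusted over the list alone), while camera pointed down (adjusted p = 0.00857, but adjusted p = 0.544 with an estimated correlation, and 0.0527 and 0.0534 without DMSO 6 h replicate 1 and 2, the libraries with mesenchymal transcripts). Of 33 enterocyte genes only Krt20 and Vil1 rose, by 0.27 and 0.19 (camera adjusted p = 0.554), also adjusted over the list alone. Both calls were lost without DMSO 6 h replicate 1 or 2 or dFz7-21 6 h replicate 1 or 3 (adjusted p from 0.0713 to 0.146), and that of Vil1 also without dFz7-21 6 h replicate 2 or 4 (0.0639 and 0.0701). The list pointed down without the 3 libraries with mesenchymal transcripts (median log2 CPM change -0.11, adjusted p = 0.0217) and without the 5 libraries named above (-0.11, adjusted p = 0.0304).

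The responses at 6 h and 24 h, which rest on different libraries, overlapped. Of the 934 genes higher at 6 h 549 were also higher at 24 h, where independent lists would share 170, and of the 771 lower at 6 h 590 were also lower at 24 h, where independent lists would share 137. Opposite calls numbered 56 and 26. Tested directly as an interaction, the dFz7-21 effect changed between the times for 2029 genes, 1137 towards higher and 892 towards lower values at 24 h. The count was 3416 in a fit of only the groups compared and 3614 without the 5 libraries that stand apart. The smallest p belonged to Olfm4 (difference of log2 changes -4.03 ± 0.19, adjusted p = 1.78e-12), followed by the tubulin Tubb2b (-1.67 ± 0.09), the chloride channel regulator Clca3b (-1.98 ± 0.12), Ces1g (1.75 ± 0.12) and the calcium pump Atp2c2 (-1.51 ± 0.11).

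The gap to DMSO widened between the times for Lgr5 (-2.61 ± 0.26, adjusted p = 3.94e-07), Axin2 (-1.17 ± 0.15), Smoc2 (-0.91 ± 0.09), Rnf43 (-0.77 ± 0.09) and Myc (-0.34 ± 0.07). Smoc2 itself was at 68.7 ± 2.92 CPM at 6 h and 135 ± 13.4 CPM at 24 h with dFz7-21, while DMSO stood at 158 ± 6.07 and 584 ± 44.4 CPM. Sp5 (-0.87 ± 0.22) and Nkd1 (-1.22 ± 0.35) passed with all libraries but not without the 3 libraries with mesenchymal transcripts (adjusted p = 0.0629 and 0.175). Nkd1 also did not pass without DMSO 24 h replicate 3, dFz7-21 24 h replicate 2 or dFz7-21 24 h replicate 3 (0.0557, 0.0553 and 0.0542). Fzd7 and Lyz1 moved down (-0.82 ± 0.17 and -0.80 ± 0.09), and Alpi, Muc2 and Chga moved up (1.13 ± 0.15, 0.72 ± 0.14 and 0.61 ± 0.16). For Ascl2 a change between the times was not shown (-0.27 ± 0.24, adjusted p = 0.547, 95% interval -0.77 to 0.24), nor for Znrf3 (-0.47 ± 0.17, adjusted p = 0.078), Mki67 (-0.22 ± 0.17) or Dclk1 (0.24 ± 0.24).

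**Figure D4:**
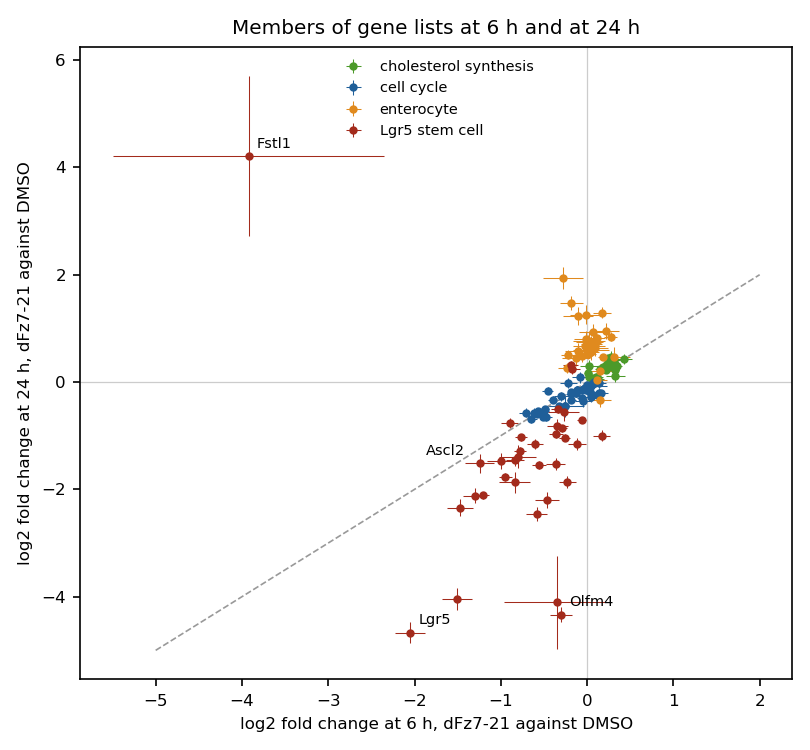
Log2 fold change of dFz7-21 against DMSO at 6 h (x axis) and 24 h (y axis) for members of the stem cell, enterocyte, cell cycle and cholesterol synthesis lists; bars are SE and the dashed line marks equal change. Olfm4 moves from -0.30 to -4.33 and Lgr5 from -2.05 to -4.67, while Fstl1 at the top left carries the mesenchymal signal of DMSO 6 h replicates 1 and 2 and dFz7-21 24 h replicate 3.

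Against Fz7-21S at 24 h, dFz7-21 lowered stem cell transcripts about as far as against DMSO. Lgr5 was 21.0-fold lower, at 3.82 ± 1.24 against 80.1 ± 18.1 CPM (SD, n = 4, log2 change -4.39 ± 0.20, adjusted p = 2.14e-13), and Olfm4 was 18.8-fold lower, at 67.9 ± 18.1 against 1274 ± 85.0 CPM (-4.23 ± 0.15). Pcdh8 (-3.50 ± 0.26), Cbs (-2.89 ± 0.12), Angpt2 (-2.75 ± 0.14), Ccdc3 (-2.70 ± 0.18), Pik3ap1 (-2.46 ± 0.16) and Msi1 (-2.37 ± 0.13) followed. Fabp6 was 4.77-fold higher (2.25 ± 0.19), and Reg3b, Itih5, Fer1l6, Oasl2, the carbonic anhydrase Car4 and the receptor Lrp1 rose by between 1.41 and 1.64. Timp3, an inhibitor of metalloproteinases, rose 2.83-fold, but stood at 31.8 CPM in dFz7-21 24 h replicate 3 and did not pass without it (0.51, adjusted p = 0.0941). In all, 5202 genes passed, 2551 higher and 2651 lower, 264 and 323 of them at least 2-fold. A fit of only the 2 groups called 2357, and 5836 were called without Fz7-21S 24 h replicate 4, which stands apart in the control group.

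Of the 17 genes followed whatever their result, Mki67 was the exception that did not pass against Fz7-21S at 24 h (0.11 ± 0.12, adjusted p = 0.531). Ascl2 fell by 1.83, Axin2 by 1.30, Smoc2 by 2.04, Sp5 by 2.28 and Nkd1 by 1.42 on the log2 scale, while Alpi rose by 1.16 ± 0.10, Muc2 by 0.93 ± 0.10 and Dclk1 by 0.78 ± 0.18. Of 34 stem cell genes 31 fell and 2 rose (median -1.29), and of 26 Wnt targets 21 fell and 1 rose (median -0.82), the same counts as adjusted over the list alone. Of the 15 Wnt targets that are not on the stem cell list 10 fell and 1 rose, as adjusted over the list alone (median -0.52, camera adjusted p = 0.000642, but adjusted p = 0.0546 with an estimated correlation). Of 25 cholesterol synthesis genes 19 rose and 0 fell, also adjusted over the list alone (median 0.23). Enterocyte genes rose in 25 of 33 cases and fell in 1 (camera adjusted p = 8.13e-11, but adjusted p = 0.211 with an estimated correlation), and Paneth genes fell in 18 of 23 cases (camera adjusted p = 7.47e-12, but adjusted p = 0.15 with an estimated correlation). Adjusted over the list alone, the counts were 25 and 1 for enterocytes and 21 lower for Paneth cells. The Paneth score of Fz7-21S 24 h replicate 4, which stands apart, was 5.87 against 5.24 to 5.43 in the other 3 controls. Cell cycle genes fell in 19 of 40 cases (21 adjusted over the list alone, camera adjusted p = 1.02e-08, but adjusted p = 0.0748 with an estimated correlation). Goblet genes had a median of -0.11, a mean of 0.08 and a camera test that pointed up without passing (adjusted p = 0.601). Oxidative and metal stress genes rose in 9 of 26 cases and fell in 4 (10 and 4 adjusted over the list alone, camera adjusted p = 0.0439, but adjusted p = 0.542 with an estimated correlation). That call was also lost without Fz7-21S 24 h replicate 1, 2 or 3 or dFz7-21 24 h replicate 2 or 4 (adjusted p from 0.0575 to 0.125). Genes of the unfolded protein and integrated stress responses rose in 8 of 26 cases and fell in 2, as adjusted over the list alone, and did not pass (median 0.05, camera adjusted p = 0.0506). They passed without Fz7-21S 24 h replicate 4 (0.00166) and without dFz7-21 24 h replicate 1, 2, 3 or 4 (0.0288, 0.0443, 0.0257 and 0.0401).

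Against Fz7-21S at 6 h, dFz7-21 gave lower Lgr5 (3.57-fold, log2 change -1.83 ± 0.18, adjusted p = 2.86e-07, n = 4), Pcdh8 (-2.57 ± 0.30), Rgcc (-1.87 ± 0.18), Scn2b (-1.70 ± 0.14), Ptpro (-1.66 ± 0.19), Sp5 (-1.53 ± 0.15), Ascl2 (-1.29 ± 0.17) and Pla2g5 (-1.27 ± 0.15). Id3 (1.57 ± 0.12), Acer1 (1.48 ± 0.17), Id1 (1.44 ± 0.13), Epb41l1 (1.40 ± 0.11), Id2 (2.38-fold), Sct (1.17 ± 0.21), the carboxypeptidase Cpm (1.11 ± 0.14) and Cyp2w1 (1.09 ± 0.18) rose. Smoc2 fell by 1.03 on the log2 scale and Rnf43 by 0.28, and Muc2 rose by 0.61 ± 0.10, while Olfm4 did not pass (-0.19 ± 0.13, adjusted p = 0.511). In all, 1086 genes passed, 495 higher and 591 lower. That count fell to 638 without dFz7-21 6 h replicate 3, 670 without dFz7-21 6 h replicate 1 and 667 without Fz7-21S 6 h replicate 2. It rose to 3159 in a fit of only the groups compared and to 2863 without the 5 libraries that stand apart. Those 5 libraries all belong to other groups, so the count of 1086 depends on libraries outside the comparison through the shared fit. Axin2 (-0.35, adjusted p = 0.0484) no longer passed on leaving out any 1 of the 8 libraries (0.0584 to 0.172), nor Myc (-0.19, adjusted p = 0.0113) without Fz7-21S 6 h replicate 2 or dFz7-21 6 h replicate 1 or 3 (0.0509 to 0.0539).

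Of 34 stem cell genes 22 fell and 0 rose against Fz7-21S at 6 h (24 lower adjusted over the list alone, median -0.50), and of 25 cholesterol synthesis genes 10 rose and 0 fell (15 higher adjusted over the list alone, median 0.20). Wnt targets fell in 12 of 26 cases and rose in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 8.54e-06, but adjusted p = 0.15 with an estimated correlation), while the 15 members that are not on the stem cell list did not pass (median 0.05, camera adjusted p = 0.98, 2 higher and 3 lower, or 2 and 4 adjusted over the list alone). BMP and TGF-beta targets rose in 7 of 19 cases and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 2.69e-06, but adjusted p = 0.0603 with an estimated correlation). Of 33 enterocyte genes 0 were called with edgeR at either adjustment, and the list did not pass (camera adjusted p = 0.231) except without dFz7-21 6 h replicate 1, where the median of its log2 CPM changes was -0.13 (adjusted p = 0.00136).

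Fz7-21S against DMSO at 24 h raised a small set of genes, among them the enzymes Cbr3, Akr1b8, Gsta2 and Cyp1a1, and gave no call for Lgr5, Olfm4 or Smoc2. Cbr3, a carbonyl reductase (chromosome 16, 93683219 to 93690991), was 1.98-fold higher, at 77.1 ± 17.1 against 38.9 ± 4.18 CPM (SD, n = 4, log2 change 0.99 ± 0.11, adjusted p = 2.25e-05). Akr1b8, an aldo-keto reductase, rose by 0.88 ± 0.09, the glutathione transferase Gsta2 by 0.98 ± 0.16, the peptide Adm2 by 1.01 ± 0.17 and the aryl hydrocarbon receptor target Cyp1a1 by 0.68 ± 0.10. Ces1g (0.61 ± 0.08), Nupr1 (0.59 ± 0.09) and Mgst2 (0.58 ± 0.12) completed the list of genes named by size. In all, 40 genes rose and 0 fell with edgeR, and DESeq2 called 105 higher and 16 lower and limma-voom 36 in all. Of 15429 genes tested with edgeR, 3673 had an unadjusted p below 0.05. That number was 1182 of 15709 without Fz7-21S 24 h replicate 4 and 639 of 14460 in a fit of only the 2 groups. The count of calls was 0 in a fit of only the 2 groups, 22 without DMSO 24 h replicate 2 and 1394 without Fz7-21S 24 h replicate 1. Mgst2 changed by 0.32 without Fz7-21S 24 h replicate 4, where it still passed (adjusted p = 0.00125), and did not pass without any 1 of the DMSO 24 h libraries (adjusted p from 0.105 to 0.2).

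Oxidative and metal stress genes rose in 8 of 26 cases and fell in 0 with Fz7-21S at 24 h (16 higher adjusted over the list alone, median 0.35, camera adjusted p = 3.65e-12). They included Gsta3 (0.57 ± 0.08), Nqo1 (0.39 ± 0.06) and Gclm, a subunit of the enzyme that makes the glutathione precursor (0.27 ± 0.04). Genes of the unfolded protein and integrated stress responses rose in 5 of 26 cases and fell in 0 (11 higher adjusted over the list alone, median 0.14, camera adjusted p = 3.51e-07), among them asparagine synthetase, Asns (0.36 ± 0.05), and Trib3 (0.47 ± 0.08). Fz7-21S 24 h replicate 4, which stands apart in its group, had the highest scores of the group for both lists, 6.27 for oxidative and metal stress and 6.77 for the unfolded protein and integrated stress responses. The other 3 libraries, at 6.06 to 6.15 and 6.62 to 6.65, were also above the 4 DMSO libraries, at 5.91 or less and 6.55 or less. Of 34 stem cell genes Phgdh, which makes serine precursors, rose and 0 fell, also adjusted over the list alone, and that call was lost without DMSO 24 h replicate 2 (adjusted p = 0.0602). The Lgr5 stem cell list pointed down (median -0.16, camera adjusted p = 0.00568, but adjusted p = 0.542 with an estimated correlation, and 0.0679 without DMSO 24 h replicate 3), with the lowest score of the group in Fz7-21S 24 h replicate 4 (5.59 against 5.82 or more). Lgr5 changed by -0.27 (95% interval -0.60 to 0.05), Olfm4 by -0.10 (-0.36 to 0.16), Smoc2 by -0.07 (-0.19 to 0.06) and Axin2 by -0.23 (-0.45 to 0.00), and none of these passed. Enterocyte (camera adjusted p = 0.00472, but adjusted p = 0.654 with an estimated correlation) and goblet genes (0.00472, but adjusted p = 0.464 with an estimated correlation) pointed up, with 0 called by edgeR and 7 and 4 higher adjusted over the list alone. Paneth (0.000808, but adjusted p = 0.551 with an estimated correlation) and enteroendocrine genes (0.0274, but adjusted p = 0.47 with an estimated correlation) pointed up too, with 1 and 0 called and 2 and 1 higher adjusted over the list alone. Both of these calls were lost without Fz7-21S 24 h replicate 4 (0.13 and 0.0557), and the enteroendocrine call without DMSO 24 h replicate 1 (0.106). The intervals of Lgr5, Olfm4, Smoc2 and Axin2 do not reach the changes of dFz7-21 against Fz7-21S given above, such as -4.39 for Lgr5, where the 2 peptides were compared directly.

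With Fz7-21S at 6 h, Cyp1a1, the aryl hydrocarbon receptor target (chromosome 9, 57687928 to 57703824), was the gene that passed against DMSO. It stood at 347 ± 13.8 against 219 ± 16.9 CPM (SD, n = 4, 1.58-fold, log2 change 0.66 ± 0.09, adjusted p = 0.00533). It did not pass without DMSO 6 h replicate 2 or 4 (adjusted p = 0.052 and 0.0659) or without the 3 libraries with mesenchymal transcripts (0.24), 2 of which are DMSO controls here. At an unadjusted p below 0.05 there were 614 of 15429 genes tested, DESeq2 called 10 and limma-voom 1. Lgr5 changed by -0.22 (95% interval -0.56 to 0.12), Olfm4 by -0.11 (-0.38 to 0.15) and Smoc2 by -0.17 (-0.30 to -0.04). The Lgr5 stem cell list pointed down (camera adjusted p = 0.00999, but adjusted p = 0.551 with an estimated correlation, 0.162 without DMSO 6 h replicate 2 and 0.0568 without Fz7-21S 6 h replicate 4). The tuft cell list (0.00847, but adjusted p = 0.202 with an estimated correlation) and the cell cycle list (4.14e-05, but adjusted p = 0.211 with an estimated correlation) pointed down too. The tuft cell call was also lost without DMSO 6 h replicate 1 (0.0509) or Fz7-21S 6 h replicate 1 (0.15). Leaving out the 3 libraries with mesenchymal transcripts lost the stem cell (0.198) and cell cycle (0.15) calls, and leaving out 5 libraries lost those (0.212 and 0.0854) and the tuft cell call (0.0576). Immediate early genes (3.55e-05, but adjusted p = 0.169 with an estimated correlation) and enterocyte genes (0.000266, but adjusted p = 0.551 with an estimated correlation, and 0.309 without DMSO 6 h replicate 1) pointed up. The enterocyte list turned to the other direction without the 3 libraries with mesenchymal transcripts (median log2 CPM change -0.0504, adjusted p = 0.0568) and without 5 libraries (-0.0518, adjusted p = 0.0285). In these 5 lists 0 genes were called by edgeR, also adjusted over the list alone. Of 26 oxidative and metal stress genes Cyp1a1 rose and 0 fell (4 higher adjusted over the list alone, camera adjusted p = 4.52e-08, but adjusted p = 0.0507 with an estimated correlation). The mesenchymal list pointed down (camera adjusted p = 1.34e-06, but adjusted p = 0.177 with an estimated correlation), with 0 of 8 members called by edgeR and 6 lower adjusted over the list alone, and Col1a1 stood at 80.6 and 10.2 CPM in DMSO 6 h replicates 1 and 2.

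Time in culture without peptide changed more genes than any treatment: 8058 genes passed between DMSO at 24 h and at 6 h, 4209 higher and 3849 lower, 891 and 753 of them at least 2-fold. Klhl24, a substrate adaptor of ubiquitin ligases (chromosome 16, 20097553 to 20129226), rose 8.25-fold, from 5.07 ± 1.13 to 42.2 ± 4.30 CPM (SD, n = 4, adjusted p = 3.83e-13). Mesothelin, Msln, rose by 2.69 ± 0.21, Prelp by 2.55 ± 0.17, the carotenoid oxygenase Bco2 by 2.52 ± 0.18 and Dmbt1, a mucosal defence protein, by 2.47 ± 0.17. Prnd, Prn and Aldh1a3 fell by 4.24, 4.02 and 3.49 on the log2 scale. Prnd and Prn cover the same span of chromosome 2 up to 131956131, so their counts are not independent. Isg15 fell by 3.31. Vim fell by 3.79, at 2.98 ± 0.557 against 40.9 ± 45.5 CPM, with 53.3 and 100.1 CPM in DMSO 6 h replicates 1 and 2. It changed by -0.79 without the 3 libraries with mesenchymal transcripts and did not pass without DMSO 6 h replicate 2 (-2.84, adjusted p = 0.0723).

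Between 6 h and 24 h in DMSO, immediate early genes fell in 22 of 27 cases and rose in 0 (23 and 1 adjusted over the list alone, camera adjusted p = 4.48e-09, but adjusted p = 0.104 with an estimated correlation), with Fos at -1.89 ± 0.08. Interferon and NF-kB genes fell in 23 of 31 cases and rose in 3 (24 and 3 adjusted over the list alone, camera adjusted p = 4.44e-06, but adjusted p = 0.128 with an estimated correlation). Cell cycle genes rose in 28 of 40 cases and fell in 6 (28 and 7 adjusted over the list alone, camera adjusted p = 5.06e-08, but adjusted p = 0.128 with an estimated correlation), with Ccnb2 at 1.56 ± 0.08. Enterocyte genes rose in 22 of 33 cases and fell in 4 (24 and 5 adjusted over the list alone, camera adjusted p = 0.000355, but adjusted p = 0.519 with an estimated correlation), with the peptide transporter Slc15a1 at 1.82 ± 0.09. Of 34 stem cell genes 17 rose and 5 fell (18 and 6 adjusted over the list alone, camera adjusted p = 0.0416, but adjusted p = 0.653 with an estimated correlation). Smoc2 rose by 1.88 ± 0.06 and Prom1 by 0.95 ± 0.05, while the hyaluronan receptor Cd44 fell by 1.40 on the log2 scale. Of the 10 lists that passed over time, 0 held with an estimated correlation, the lowest adjusted p being 0.104.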

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

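Mesenchymal transcripts such as Col1a1 and Vim were high in DMSO 6 h replicates 1 and 2 and dFz7-21 24 h replicate 3. Of the tests here, the one on an effect of dFz7-21 was chosen after the result was seen. Mesenchymal cells in those libraries could account for it. Of the 22 genes of the fixed mesenchymal list, 14 were above the highest of the other 21 libraries in all 3. Not every marker was present: Dcn and Lum stood at 0 CPM in these 3 libraries and Thy1 at 0.243 CPM or less. Of 28 further mesenchymal genes, 23 reached 1 CPM in any library, and most of these did so only in the 3 libraries themselves. Of the 23, 20 (87.0%) were at least 5-fold above the other 21 libraries in dFz7-21 24 h replicate 3, and 13 in each of the DMSO 6 h libraries. The other 3 dFz7-21 24 h libraries did not share the high levels. Their mesenchymal list differed from DMSO 24 h by a median of 0.11 on the log2 scale (interval 0.03 to 0.51, from a bootstrap over genes). The test asked for a difference of at least 1 in libraries already seen to be low, so a smaller effect of dFz7-21 is not excluded. Each flagged library has an outlier value, given bare in parentheses here and in the paragraphs on outlying libraries below. It is the gap to the nearest library of the group divided by the range of the group, and not a p-value. In dFz7-21 24 h replicate 3 the mesenchymal score was 6.63 against 0.90 or less in its group (0.923), with higher BMP and TGF-beta (0.898), immediate early (0.853) and p53 (0.949) scores and Fzd7 at 40.6 against 27.5 CPM or less (0.86).

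Fz7-21S 24 h replicate 4 stood apart from the other libraries of its group. The tests on transcript length and on a wrong label were chosen after the result was seen. It had a lower stem cell score (5.59 against 5.82 or more, 0.953), higher enteroendocrine (0.866) and unfolded protein and integrated stress (0.836) scores, and more counts in ribosomal protein genes (2.13%, 0.89) and unnamed IDs (3.50%, 0.832). A bias by transcript length could account for it, with a Spearman correlation of -0.56 over 14049 genes, against 0.29, -0.07 and -0.20 in replicates 1 to 3. A bias by GC content cannot be told (0.22, against -0.29, -0.27 and 0.48). A dFz7-21 library under a wrong label is excluded, because Olfm4 was 13.4-fold and Lgr5 11.5-fold above the highest dFz7-21 24 h library, and no biological explanation was tested.

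The stem cell and Paneth lists were lower and the enterocyte list higher with dFz7-21 at 24 h. With an estimated correlation the Paneth and enterocyte calls were lost (adjusted p = 0.312 and 0.15). Both tests of this pattern were chosen after the result was seen. Enterocyte and Paneth genes differed by 1.28 in mean log2 change. The permutation p was 1e-05 across genes and 0.0286 over the 8 libraries, each the smallest possible with its permutations. The permutation across genes treats the members of a list as independent. Both p-values test a difference already seen in the pattern. They therefore cannot by themselves exclude a smaller share of stem cells with every other cell type scaled up alike. Such scaling would raise Paneth genes. The Paneth list was lower, but that call was lost with an estimated correlation. The library with mesenchymal transcripts is excluded as the source, because the stem cell list kept a median log2 CPM change of -1.39 without the 3 libraries. An altered choice of fate or a loss of Paneth cells may both be at work and stays open.

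Chance alone would mark about 1 in 20 groups for an outlying library, or 13.5 of the 270 examined, and 23 were found, 10 of which are in the paragraphs above. DMSO 6 h replicate 2 had higher Wnt receptor and ligand scores (0.919) and Rnf43 (169 CPM, 0.837), and lower goblet (0.898) and Paneth (0.908) scores and Muc2 (108 CPM, 0.908). DMSO 24 h replicate 2 had 16897 genes with a read against 19148 or more (0.871), and DMSO 24 h replicate 3 a lower cell cycle score (6.58, 0.924). The enterocyte score of dFz7-21 6 h replicate 1 was 6.62 against 6.34 or less (0.832), and Mki67 in dFz7-21 6 h replicate 3 was 193 CPM against 205 or more (0.876). Lgr5 was 44.3 CPM in Fz7-21S 6 h replicate 2 (0.872), Nkd1 5.10 CPM in DMSO 6 h replicate 4 (0.879) and Alpi 69.1 CPM in Fz7-21S 24 h replicate 3 (0.896). The immune score of Fz7-21S 6 h replicate 4 was 0.15 against 0.48 or more (0.884).

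The dFz7-21 effect changed between 6 h and 24 h for 2029 genes. Those with the smallest p were Olfm4 (-4.03), Tubb2b (-1.67), Clca3b (-1.98), Ces1g (1.75) and Atp2c2 (-1.51). Of the genes followed throughout, Lgr5 (-2.61), Axin2 (-1.17), Smoc2 (-0.91), Sp5 (-0.87), Nkd1 (-1.22), Rnf43 (-0.77), Myc (-0.34), Fzd7 (-0.82) and Lyz1 (-0.80) moved down and Alpi (1.13), Muc2 (0.72) and Chga (0.61) moved up. Nkd1 did not pass without DMSO 24 h replicate 3, dFz7-21 24 h replicate 2 or dFz7-21 24 h replicate 3 (adjusted p = 0.0557, 0.0553 and 0.0542).

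Only 1 of 35 splits of the 8 libraries, the real one, gave as many calls in each comparison of groups. That is the lowest share these splits can reach. The other splits mix both groups under each label, which widens the spread within a label where the groups differ. They tend to give few calls for that reason, so they do not exclude chance by themselves. The 40 calls for Fz7-21S against DMSO at 24 h were 0 in a fit of only those groups. The real count and the highest other were 5537 and 99 for dFz7-21 against DMSO at 24 h, 1705 and 0 at 6 h, 5202 and 2081 for dFz7-21 against Fz7-21S at 24 h, and 1086 and 0 at 6 h. For Fz7-21S against DMSO they were 40 and 1 at 24 h, and for DMSO over time 8058 and 2. For Fz7-21S against DMSO at 6 h they were 1 and 0, and that call, Cyp1a1, was lost without DMSO 6 h replicate 2 or 4 (adjusted p = 0.052 and 0.0659). For the change between times 3 of 100 splits gave as many calls, with 2029 in the real one and 4172 and 2637 in the others. In both of those the 24 h labels of dFz7-21 and DMSO were fully exchanged, so they hold the real 24 h contrast.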

How the results depend on the processing

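With a minimum fold of 1.2 the counts of calls fell to 2047 and 259 for dFz7-21 against DMSO at 24 h and 6 h, 1689 and 121 for dFz7-21 against Fz7-21S, 2 and 0 for Fz7-21S against DMSO, 4566 for DMSO over time and 799 for the change between times, because that test asks for more than a difference from 0. A fit of only the groups compared gave 3640 for dFz7-21 against DMSO at 6 h, 2357 and 3159 for dFz7-21 against Fz7-21S at 24 h and 6 h, 0 and 4 for Fz7-21S against DMSO and 3416 for the change between times. Such a fit drops the spread of the other groups and also changes the filter and the size factors, and these were not tested apart. DESeq2 gave 121 and 10 for Fz7-21S against DMSO. With the replicate number as a block the counts were 5276, 1645, 5068, 990, 42, 1, 5639 and 1818 in the order above, and of 24 same-numbered pairs 1 had a correlation above 0.1, so the numbers do not pair the libraries. The blocks were set within each time, with replicate 1 as the reference. The count of 5639 for DMSO over time therefore compares the levels of replicate 1, and not the group means.

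Leaving out 1 library of the groups compared gave 4846 to 5171 and 1172 to 1636 calls for dFz7-21 against DMSO at 24 h and 6 h, 4363 to 5836 and 638 to 897 for dFz7-21 against Fz7-21S, 22 to 1394 and 0 to 1 for Fz7-21S against DMSO, 7408 to 7667 for DMSO over time and 1771 to 2073 for the change between times. Low values were 638 without dFz7-21 6 h replicate 3, 667 without Fz7-21S 6 h replicate 2, 670.0 without dFz7-21 6 h replicate 1, 22 without DMSO 24 h replicate 2 and 0 without DMSO 6 h replicate 2 or 4. The high value of 1394 came without Fz7-21S 24 h replicate 1. Among named genes 111 calls were lost, 35 gained and 5302 unchanged when libraries of the groups compared were left out. Libraries of other groups share the fit, and leaving out 1 of them was not counted.

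Leaving out sets of libraries, and the test of Wnt targets that are not on the stem cell list, were chosen after the data were seen. Without the 3 libraries with mesenchymal transcripts 698 genes were called for dFz7-21 against DMSO at 6 h and 0 for Fz7-21S against DMSO at 6 h. DMSO 6 h replicates 3 and 4 are then the only controls at 6 h. Without 5 libraries that stand apart (those 3, Fz7-21S 24 h replicate 4 and DMSO 24 h replicate 2) the counts were 2236 for dFz7-21 against DMSO at 6 h, 2863 for dFz7-21 against Fz7-21S at 6 h, 0 for Fz7-21S against DMSO at 6 h and 3614 for the change between times. For dFz7-21 against DMSO at 6 h both settings keep the same 6 h libraries, so 698 and 2236 differ through the shared fit. For dFz7-21 against Fz7-21S at 6 h all 5 libraries lie outside the comparison.

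Of 57 list calls 13 held with an estimated correlation, and leaving out 1 library gave 56 to 61. Among the calls lost with an estimated correlation were those of enterocytes at 24 h against DMSO and Fz7-21S. Their median log2 CPM changes were 0.71 (adjusted p = 0.15) and 0.56 (0.211). The calls of Wnt targets at 6 h were lost too, at -0.22 (0.169) and -0.21 (0.15). Wnt targets that are not on the stem cell list stood at 0.0438 (0.819) against DMSO and 0.0543 (0.98) against Fz7-21S at 6 h, so the 6 h calls rest on the shared members. Enterocytes in dFz7-21 against DMSO at 6 h stood at -0.11 without 3 libraries (0.0217) and -0.11 without 5 (0.0304). Against Fz7-21S they ran from -0.13 (0.00136, without dFz7-21 6 h replicate 1) to -0.0145. For Fz7-21S against DMSO at 6 h the enterocyte list reversed from 0.0899 (0.000266) to -0.0504 without 3 (0.0568) and -0.0518 without 5 libraries (0.0285), and the cause was not tested.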

Other observations

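The early and late responses to dFz7-21 also overlapped when Fz7-21S was the control. Of 591 genes lower at 6 h, 449 were lower at 24 h, where independent lists would share 102, and of 495 genes higher at 6 h, 291 were higher at 24 h, where independent lists would share 81.8. Opposite calls numbered 20 and 33. Lgr5, the stem cell receptor, and Pcdh8, a protocadherin, were among the genes lower at both times (-1.83 ± 0.18 and -2.57 ± 0.30 at 6 h, -4.39 ± 0.20 and -3.50 ± 0.26 at 24 h). Id3, a target of BMP signalling whose value is uncertain because 2 other gene models hold the same values, was higher at both (1.57 ± 0.12 and 1.13 ± 0.12).

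Of the 40 genes that rose with Fz7-21S at 24 h, among them Cbr3 and Akr1b8, 38 also rose with dFz7-21 against DMSO. Between the peptides, 18 of the 40 were higher and 4 lower with dFz7-21 than with Fz7-21S. The tests of this were chosen after the result was seen. With the DMSO 24 h libraries split so that each peptide had its own controls, the 40 genes most raised with Fz7-21S had a median log2 change of at least 0.37 with dFz7-21 in each of 6 splits, against at most 0.14 at the upper end of the central 95% of random genes of like level. At 6 h the 40 called genes had a median of 0.0861 with Fz7-21S, above the random range of 0.00 to 0.04. A difference common to all DMSO 24 h libraries would pass every split, so the splits cannot tell it from an effect of the peptides. Both peptides may share an effect on enzymes such as Cbr3, of a size that differs for some of the genes, and a set of cultures with an unrelated peptide would test it.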
